A study of Mus musculus with 16 samples.

How the data were processed

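RNA was extracted from 6DT1 cells with a Qiagen RNeasy kit and made into Illumina libraries, per the labels' protocols. The deposited tables hold gene counts and FPKM for 16 libraries. Reads were trimmed with cutadapt, aligned with STAR and quantified with RSEM on the mouse genome build mm10, per the submitters' processing notes; versions, the order of steps, the gene annotation and strandedness are not given in the sources used here. The authors' count table holds whole numbers for 25745 genes. RSEM gives expected counts, so the deposited counts may have been rounded by the authors. The deposited FPKM values for 25372 genes are scaled by the authors to gene length and library depth. Without known strandedness, overlapping and antisense genes cannot be told apart, and reads of near-identical copies and pseudogenes may be split between genes.

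Groups came from the sample titles: empty vector or CLIC4 lentivirus, each untreated or treated, with 4 libraries each. Total counts ran from 47.1 M to 61.9 M. Within groups, correlations over genes were at least 0.9989 apart from library 11, and no pair of libraries had counts equal within sampling noise, since the lowest chi-square per degree of freedom was 5.3. Gene positions were taken from the mm10 annotation GENCODE vM21 by gene symbol, and all 25745 symbols matched.

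The main test, fixed before the data were examined together with its alternatives, was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3). One robust fit held all 16 libraries with a coefficient per group, so that groups share an estimate of the spread, with TMM scaling and filterByExpr, which left 14445 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and a further count asked for at least 2-fold. Standard errors were the log2 change divided by the square root of F. The 5 comparisons were empty vector minus lentivirus in untreated and in treated cells, treated minus untreated in each kind of cell, and the difference of these responses. No replicate block was used, since no library number is shared by groups. Levels are TMM-scaled CPM unless stated otherwise. Where a group had 0 counts, folds used a floor of 3 counts over the group, and with 1 to 3 counts a ratio with its exact 95% counting interval is given. Intervals and floors cover counting error only.

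The 31 gene lists, covering oxidant defence, stress responses, mitochondria, metabolism, cell cycle, signalling, cell identity and markers of other cell types, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, 2-sided, adjusted over the lists of a comparison. An estimated correlation and fry were alternatives. Named genes followed a fixed rule. It took the 8 genes rising and the 8 falling most (5 and 5 for the difference of responses) among called genes with an average log2 CPM of at least 2, groups that do not overlap and a regular symbol. It added the CLIC family, up to 4 members of each called list by smallest adjusted p, with ties in the order of the list (in the H2O2 comparisons most members tie), and 10 oxidant and stress genes in the H2O2 comparisons. The text names part of these, and says where it goes outside the rule.

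Other alternatives were RLE size factors, DESeq2 1.42.0, no filter, a filter of 10 CPM in 4 libraries, a fit on the compared groups alone, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with FPKM of at least 0.5 in 4 libraries, log2(FPKM + 1) without a filter, and leaving out each library in turn. Fold changes on the log2(FPKM + pseudocount) scale understate the change of low genes. After library 11 was seen, limma voom with library quality weights was added, and a fit without library 11 with the mitochondrial mRNA share as a covariate. Shares of mitochondrial mRNA were compared by exact permutation tests. The tests were checked on simulated counts with 50 genes changed at each of 4 fold sizes, 6 times per comparison, since recovery differs between draws. Each gene had a mean pooled over the libraries without library 11, whose own departure was kept. Genes changed at these fold sizes had a mean of at least 4 CPM, and genes were drawn independently. Apart from changed genes and library 11 the simulated groups did not differ, unlike the real vectors. Recovery and shares of false calls may therefore not carry over to the real comparisons. With 16 libraries, edgeR recovered 40% to 50% of genes changed 1.5-fold and 88% to 98% of genes changed 4-fold in untreated empty vector minus lentivirus, with 0% to 1.69% of its calls on unchanged genes, and 3.23% to 8.61% without library 11. Figures were drawn with matplotlib 3.10.9.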

Results

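Gene expression was measured by RNA-seq in 16 libraries of 6DT1 cells, a mouse mammary cancer cell line. The cells carried a lentivirus made to express CLIC4, a chloride intracellular channel family protein, or an empty vector, and were left untreated or given 1 µM hydrogen peroxide (H2O2) for 24 h. Each of the 4 groups held 4 libraries, with total counts between 47.1 M and 61.9 M. The labels give conflicting accounts of the genotype. The sample descriptions call the empty-vector libraries CLIC4 knockout and the lentivirus libraries wild type, while the series text speaks only of the vectors. Nothing in the labels says that the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The title of the series names mitochondrial function and resistance to oxidants as its subject.

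Library 11, an untreated empty-vector library, stood apart from the other libraries of its group. Its correlation with them over genes reached at most 0.956, while no other pair within a group was below 0.9989. Of 11816 expressed genes, 1861 were at least 2-fold higher and 2426 at least 2-fold lower in library 11 than the mean of libraries 9, 10 and 12. Structural RNA took 3.05% of its counts, against 0.202% to 0.248% in libraries 9, 10 and 12. The planned comparisons keep library 11, and leaving it out was an alternative fixed with the design. With library 11 the biological coefficient of variation was 23.1%, and without it 5.28%.

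**Figure D1:**
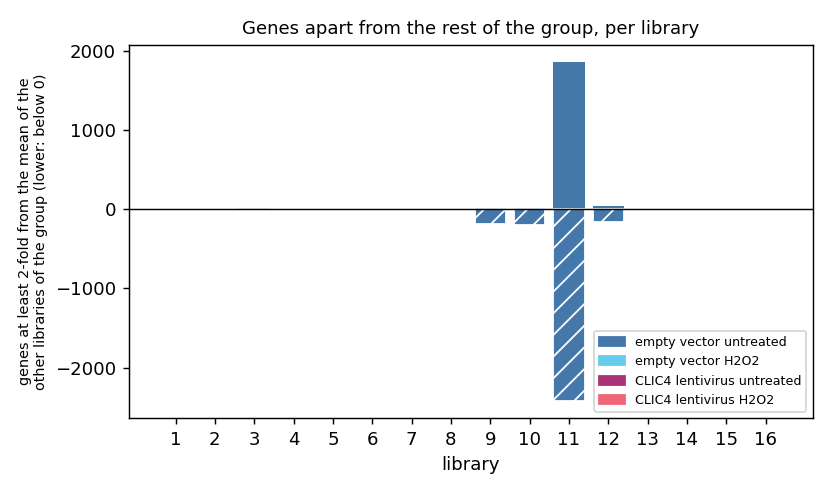
Bars give, for each of the 16 libraries (x axis), the number of expressed genes at least 2-fold higher (above 0) or at least 2-fold lower (hatched, below 0) than the mean of the other libraries of its group (y axis), coloured by group. Library 11 had 1861 higher and 2426 lower genes, and libraries 9, 10 and 12 had 161 to 202 lower genes against means that include library 11.

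Clic4 itself (chromosome 4, 135213969 to 135272814, mm10) was lower in the empty-vector libraries. In untreated cells it reached 66.3 ± 47.8 TMM-scaled CPM with the empty vector and 229 ± 10.4 CPM with the lentivirus (SD, n = 4 each). The log2 change was -1.79 with a standard error of 0.313 (edgeR adjusted p = 2.88e-04). Library 11 held 138 CPM of Clic4, and without it the log2 change was -2.43. In treated cells the levels were 42.4 ± 2.35 and 243 ± 12.9 CPM (SD, n = 4 each), a log2 change of -2.52 with a standard error of 0.322 (edgeR adjusted p = 1.78e-05). H2O2 left Clic4 without a call in the empty-vector cells (log2 change -0.65, edgeR adjusted p = 0.341; -0.00 without library 11, where the adjusted p was 0.995) and in the lentivirus cells (0.09, edgeR adjusted p = 1). Counts of the transferred and the resident gene cannot be separated in the table.

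**Figure D2:**
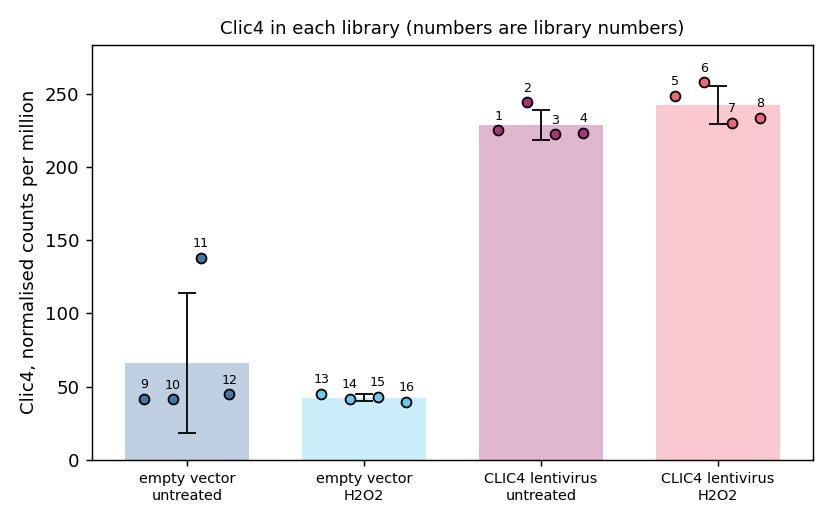
Points give Clic4 in TMM-scaled CPM (y axis) in each library, numbered, for the 4 groups (x axis); bars are group means and error bars 1 SD. The lentivirus groups average 229 and 243, the treated empty-vector group 42.4, and library 11 lies at 138 in the untreated empty-vector group.

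The other measured members of the family were Clic1 and Clic5. Clic1 was higher in empty-vector cells, by a log2 change of 0.22 (edgeR adjusted p = 0.0331) in untreated and 0.34 (adjusted p = 0.00289) in treated cells. Clic5 was near the detection limit, with 3 counts over the untreated and 2 over the treated lentivirus libraries. Its ratio of empty vector to lentivirus was 19.5 (counting interval 6.33 to 97.2) untreated, with a log2 change of 4.17 that was 3.48 without library 11 and 5.17 without library 4, and 17.8 (4.59 to 153) treated. The untreated Clic1 call rests on a small difference. It ended when library 1, 3, 9, 10 or 12 was left out (log2 change 0.20, 0.19, 0.19, 0.17 and 0.19; edgeR adjusted p = 0.0782, 0.0945, 0.083, 0.0961 and 0.0759), with no filter (0.21, adjusted p = 0.122), with the 10 CPM filter (0.17, 0.0794) and with the compared groups alone (0.22, 0.153). It also ended with limma on log2(FPKM + 0.1) (0.12, adjusted p = 0.544) and log2(FPKM + 1) (0.12, 0.543; 0.609 without a filter), which did not call the treated difference either (0.36, adjusted p = 0.085 and 0.0822; 0.134 without a filter). Treated Clic5 was not called on log2(FPKM + 1) without a filter (adjusted p = 0.0827). The family as a list was not called.

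In untreated cells, the empty-vector libraries had high levels of transcripts that were nearly undetected with the lentivirus. Srgn, the proteoglycan serglycin, reached 233 ± 158 CPM against 0.0548 ± 0.0119 (SD, n = 4 each), and Anpep, the cell surface aminopeptidase N, 73.1 ± 30.2 against 0.0318 ± 0.0162. Gsdmd, the pore-forming gasdermin D, stood at 40.1 ± 13.1 against 0.0186 ± 0.0251 CPM. In the other direction, Slitrk5 (0.154 ± 0.106 against 90.2 ± 1.89 CPM), Slc40a1, the iron exporter ferroportin (0.0611 ± 0.0514 against 54.4 ± 0.844), and Fam135b (0.0652 ± 0.0713 against 39.7 ± 3.1) were nearly lost from the empty-vector cells. Pkia, an inhibitor of protein kinase A, had 0 counts in the 4 untreated empty-vector libraries and 2006 in the lentivirus libraries, at least 641-fold lower. Library 11 had the highest Srgn level, and without it the log2 change of Srgn was 11.39 in place of 11.99; for Fam135b it was -10.04 in place of -9.35. Of the 4 Gsdmd counts in lentivirus libraries 3 lie in library 3, and without it the log2 change was 12.20 in place of 10.92.

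The remaining genes taken by size were Gfpt2 (log2 change 11.90), Fcho1 (8.99) and Sprr1a (9.63) among those higher, with edgeR adjusted p = 1.54e-06, 3.78e-09 and 0.00198. Library 11 carried most of the Sprr1a counts, and without it the log2 change of Sprr1a was 3.25 and that of Gfpt2 10.09. With limma on log2(FPKM + 1) Sprr1a was not called (2.33, adjusted p = 0.0936; 0.155 without a filter). Wfdc2 and Uox, the urate oxidase, rested on 2 and 1 counts in the lentivirus libraries, for ratios of 1595 (counting interval 441 to 13170) and 1731 (310 to 68430); the count of Uox lies in library 4, and without it Uox is at 0. Lower were Gxylt2 (-9.35), Nrk (-9.23), Tmtc2 (-8.77) and Fhit (-7.88), with adjusted p between 2.18e-11 and 4.15e-09; without library 11 Nrk was at -11.59 and Tmtc2 at -10.28. In every one of these genes the libraries of one group all lay above those of the other, as the rule for naming them required.

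By edgeR, 4184 genes were higher and 3516 lower in untreated empty-vector cells at an adjusted p under 0.05, of 14445 tested. At least 2-fold, 1741 were higher and 1417 lower. Without library 11 the counts were 5409 higher and 5449 lower; of the 7700 called with all libraries, 7511 were also called in the same direction without library 11 and 16 in the opposite direction. A fit on the untreated libraries alone called 2430 higher and 1996 lower.

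Cell cycle genes were higher in untreated empty-vector cells. All 26 measured DNA replication genes were called higher (26 adjusted over the list alone), with a median log2 change of 1.23, among them Ccne1, cyclin E1 (2.55), and Mcm3, a subunit of the replicative helicase (1.47). Of 25 genes of G2 and mitosis, 23 were higher (24 adjusted over the list alone), such as Aurka (1.25) and Cdc20 (0.96); without library 11, 26 and 25 were higher. The preset camera test called both lists (adjusted p = 4.89e-13 and 4e-08), but adjusted p = 0.374 with an estimated correlation for DNA replication and adjusted p = 0.542 with an estimated correlation for G2 and mitosis.

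Stress response genes were also higher. Of 29 measured targets of ATF4, the transcription factor of the integrated stress response, 24 were higher and 1 lower (the same counts adjusted over the list alone), with a median of 1.08. They included the amino acid and one-carbon enzymes Asns (2.07), Shmt2 (1.19) and Mthfd2 (3.14). Of 23 genes of the unfolded protein response of the endoplasmic reticulum, 20 were higher (22 adjusted over the list alone), with a median of 0.90, including Sdf2l1 (2.17), Edem1 (1.45) and Hsp90b1 (0.83). The camera calls held, with adjusted p = 0.0482 with an estimated correlation for ATF4 targets and adjusted p = 0.0244 with an estimated correlation for the unfolded protein response. Without library 11 both estimates rose to adjusted p = 0.209, with 24 ATF4 targets higher and 3 lower and 22 unfolded protein response genes higher.

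NF-kB target genes and immediate early genes were called as lists too, and library 11 carried much of their size. Of 16 measured NF-kB targets, 12 were higher (12 adjusted over the list alone), with a median of 2.94 that fell to 0.87 without library 11. Of 19 immediate early genes, 14 were higher (15 adjusted over the list alone), with a median of 2.40 against 1.00 without library 11. Vcam1 (2.78; 2.96 without library 11) and Fosl1 (3.19; 3.31) kept their size, while the chemokine gene Ccl2 (5.18; 2.80) and Nr4a1 (4.00; 2.64) did not. Without library 11, 11 NF-kB targets were higher and 1 lower, and 15 immediate early genes were higher and 3 lower. Both lists had adjusted p = 0.542 with an estimated correlation.

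Ribosomal protein genes and genes of respiratory complex I were lower in untreated empty-vector cells. Of 80 cytosolic ribosomal protein genes, 49 were called lower and 0 higher (53 lower adjusted over the list alone), with a median of -0.52, including Rpl3 (-0.75) and Rpl22 (-0.76); without library 11, 78 were lower. Of the 37 nuclear genes of complex I, 20 were lower and 0 higher (20 adjusted over the list alone), with a median of -0.26, including Ndufa6 (-0.63); without library 11, 29 were lower. The preset camera calls (adjusted p = 4e-08 and 0.00418) were not kept, at adjusted p = 0.622 with an estimated correlation for ribosomal proteins and adjusted p = 0.529 with an estimated correlation for complex I. Many ribosomal protein genes have processed pseudogenes that can share their reads. Without library 11 the preset camera test called 14 lists in place of 8. It added NRF2 targets (adjusted p = 0.044), complexes II to IV (0.044), mesenchymal (0.0256) and basal genes (9.34e-06) and markers of immune (0.0234) and endothelial cells (0.00695). Complexes II to IV and endothelial markers were called lower, and the other added lists higher. The basal and immune lists held only 3 measured genes each, with 2 higher and 1 lower in each. The endothelial list held 5, with 1 higher and 3 lower. None of the added lists was kept, at adjusted p = 0.173, 0.69, 0.209, 0.0949, 0.173 and 0.158 with an estimated correlation.

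In treated cells the same kinds of genes separated the vectors. Anpep reached 83.9 ± 1.75 CPM with the empty vector against 3 counts over the 4 lentivirus libraries (ratio 6394, counting interval 2188 to 31010), Srgn 153 ± 6.49 against 0.0496 ± 0.043 CPM, and Gsdmd 47.3 ± 0.546 against 0.018 ± 0.0361 CPM (SD, n = 4 each). Tnfsf13b, the B cell activating factor BAFF (log2 change 9.56), Wfdc2 (8.74) and the chemokine receptor gene Ccr4 (8.71) were also higher. Lower were Slitrk5 (-9.18), Slc40a1 (-9.12), Fam135b (-8.76) and Cgn, the tight junction protein cingulin (-8.06). Pkia had 0 counts with the empty vector, at least 706-fold lower. Ratios with 1 to 3 counts on one side were 6218 for Gfpt2 (counting interval 1116 to 245600) and 614 for Uox (210 to 2981), both higher with the empty vector, and lentivirus to empty vector 6679 for Nrk (1198 to 263800), 2867 for Tmtc2 (793 to 23680) and 988 for Cyp39a1 (273 to 8167). The counts of Gfpt2 lie in library 8 and those of Nrk and Tmtc2 in library 14, so that without these libraries the genes are at 0, as is Gsdmd without library 6. The log2 change of Srgn was 11.57, and 12.29 without library 5; Ccr4 was at 9.69 without library 8, and without library 13 Slc40a1 was at -9.91 and Fam135b at -9.48.

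By edgeR, 3189 genes were higher and 2890 lower in treated empty-vector cells, and at least 2-fold 1391 and 1096. Leaving out library 11, which belongs to neither group compared, gave 5347 higher and 5432 lower, since the groups share one estimate of the spread. All 6079 genes called with 16 libraries were then called in the same direction. A fit on the treated libraries alone called 5183 higher and 5308 lower.

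Lists of cell cycle, stress and ribosomal genes were called in the same directions as in untreated cells. All 25 genes of G2 and mitosis (median 1.33, Aurka 1.48) and 25 of 26 DNA replication genes (median 1.38, Ccne1 2.57) were higher, with 25 and 26 adjusted over the list alone. The estimates were adjusted p = 0.438 with an estimated correlation for G2 and mitosis and adjusted p = 0.2 with an estimated correlation for DNA replication. Of ATF4 targets 19 were higher and 2 lower (20 and 2 adjusted over the list alone; Asns 2.10, Mthfd2 2.92), with adjusted p = 0.0818 with an estimated correlation. Of unfolded protein response genes 19 were higher (20 adjusted over the list alone; Sdf2l1 2.33), with adjusted p = 0.038 with an estimated correlation, and 0.277 without library 11. Of ribosomal protein genes 73 of 80 were lower (75 adjusted over the list alone; Rpl3 -0.79), with adjusted p = 0.656 with an estimated correlation. Of complex I genes 12 were lower (11 adjusted over the list alone; Ndufa6 -0.73), with adjusted p = 0.584 with an estimated correlation; without library 11, 26 of 37 were lower (26 adjusted over the list alone). NF-kB targets (5 of 16 higher, 4 adjusted over the list alone, adjusted p = 0.103) and immediate early genes (6 of 19 higher, 5 adjusted over the list alone, adjusted p = 0.0554) were not called by camera with 16 libraries. Without library 11, 11 NF-kB targets were higher and 3 lower and 15 immediate early genes were higher and 3 lower, the same adjusted over the list alone. Also without it, 24 ATF4 targets were higher and 2 lower, 22 unfolded protein response genes were higher and 77 ribosomal protein genes lower. The preset test without library 11 did call NF-kB targets (adjusted p = 0.00866), immediate early genes (0.00208), basal genes (6.04e-05) and immune markers (0.0391) higher. It called endothelial markers lower (0.00273), and no longer called the complex I list (0.0545). Each of these 5 calls had adjusted p = 0.18 with an estimated correlation. The basal and immune lists held only 3 measured genes each, with 2 higher and 1 lower in each. The endothelial list held 5, with 1 higher and 3 lower.

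**Figure D3:**
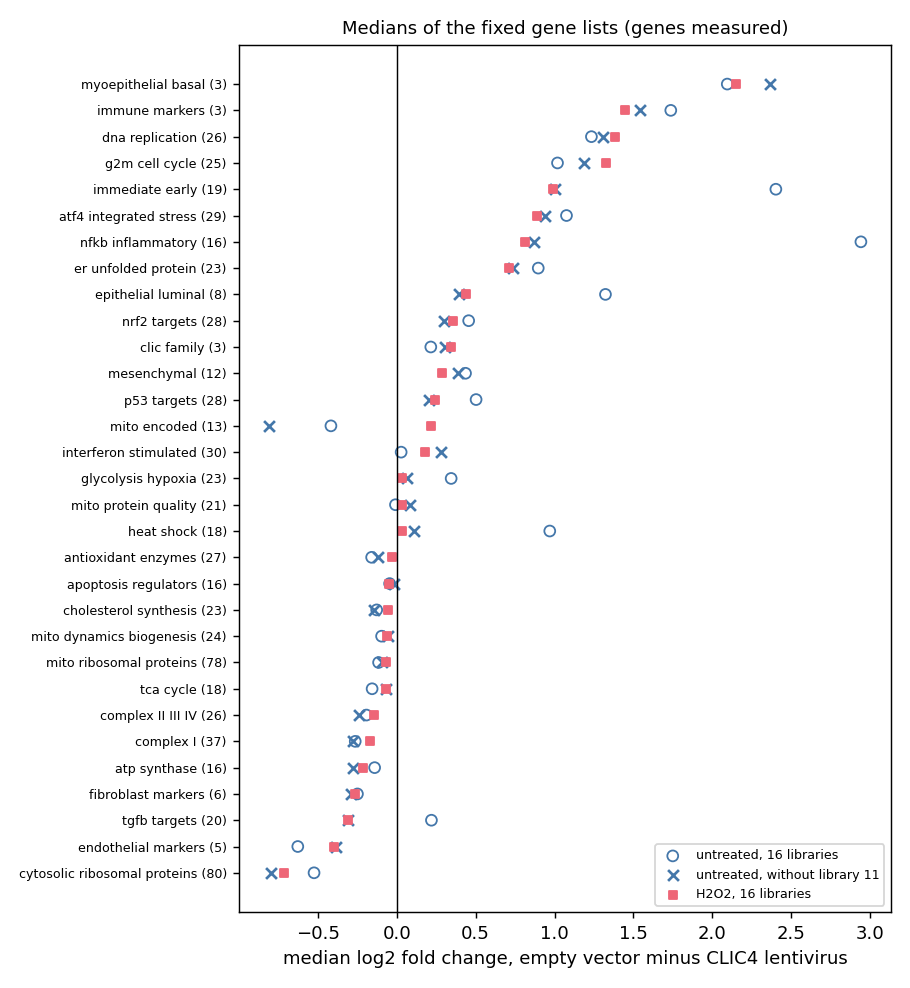
Each line is 1 of the 31 fixed gene lists (y axis, genes measured in parentheses) and the x axis its median log2 change, empty vector minus lentivirus, in untreated cells with 16 libraries (circles) and without library 11 (crosses) and in treated cells (squares). DNA replication lies at 1.23 and 1.38 with 16 libraries, cytosolic ribosomal proteins at -0.52 and -0.71, and NF-kB targets at 2.94 in untreated cells against 0.87 without library 11.

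The genes called between the vectors were largely shared by the untreated and treated comparisons. Of the genes called higher, 2822 were higher in both, against 924 for independent lists, and of those called lower 2357, against 703, with 0 called in opposite directions. Without library 11 there were 4859 higher and 4721 lower in both, against 1981 and 2027 for independent lists, and 18 and 12 called in opposite directions. The log2 changes of the comparisons correlated over genes at r = 0.897 (0.957 without library 11), where genes are not independent replicates. The comparisons share no library.

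With H2O2, the planned edgeR test called no gene in the empty-vector cells, while other fits named below did call some. The oxidant and stress genes fixed in advance were not called: Hmox1, heme oxygenase 1 (log2 change -0.39), Nqo1 (-0.47), Txnrd1 (-0.34), Gclm (0.01), Cat, the catalase (0.18), Sod2 (-0.11), Cdkn1a (-0.42), Atf4 (-1.05), Ddit3 (-0.29) and Gdf15 (-1.09). Levels of Hmox1 were 36.8 ± 5.58 CPM treated and 48.3 ± 23.8 CPM untreated (SD, n = 4 each). Without library 11 the changes of these 10 genes lay between -0.05 (Cdkn1a) and 0.08 (Nqo1), with 0.01 for Hmox1, -0.01 for Atf4, 0.07 for Gdf15 and -0.05 for Gclm, and the smallest adjusted p was 0.349. Clic1 (0.06) and Clic5 (-0.88; -0.18 without library 11) were not called.

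The edgeR test called 0 genes in each direction, with 2120 at an unadjusted p under 0.05. DESeq2 called 27 higher and 11 lower, limma on log2 FPKM called 0, and limma voom with library weights, chosen after the data were seen, 72 and 44. Without library 11 edgeR called 18 higher and 17 lower, and without library 14 it called 1 higher and 0 lower. Without library 11 and with the mitochondrial mRNA share as a covariate, a fit chosen after the data were seen, it called 0 and 0, with 687 at an unadjusted p under 0.05. Among these libraries that share ran from 2.3% to 2.95% in treated and from 1.08% to 1.43% in untreated empty-vector cells. The covariate therefore takes up part of the treatment difference itself, and the lost calls do not show that the share explains them. A fit on the compared libraries alone called 0 genes, and 329 when library 11 was left out of it. Over 6 simulated data sets, edgeR with 16 libraries recovered 42% to 66% of genes changed 1.5-fold in this comparison, and without library 11 94% to 100%, where 2.11% to 8.37% of all calls were of unchanged genes.

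Mitochondrially encoded mRNA took 2.65 ± 0.312% of counts in treated and 1.57 ± 0.575% in untreated empty-vector libraries (SD, n = 4 each). The exact permutation p was 0.0571, 2-sided, and 0.143 when adjusted over the 5 tests of this share. Without library 11, at 2.41%, the untreated share was 1.3 ± 0.188% (SD, n = 3; exact permutation p = 0.0286, the smallest the design allows, adjusted 0.143). In lentivirus cells the shares were 2.06 ± 0.614% treated and 2.08 ± 0.916% untreated (SD, n = 4 each; exact permutation p = 1). In the list of 13 such genes, 0 were called over all genes and 4 were higher adjusted over the list alone (10 without library 11), with members such as mt-Nd5 (log2 change 1.16) and mt-Nd2 (0.94), both subunits of complex I. The list median was 0.52 (1.03 without library 11), called by the preset camera test (adjusted p = 8.39e-04; 0.0647 without library 10) and at adjusted p = 0.68 with an estimated correlation.

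**Figure D4:**
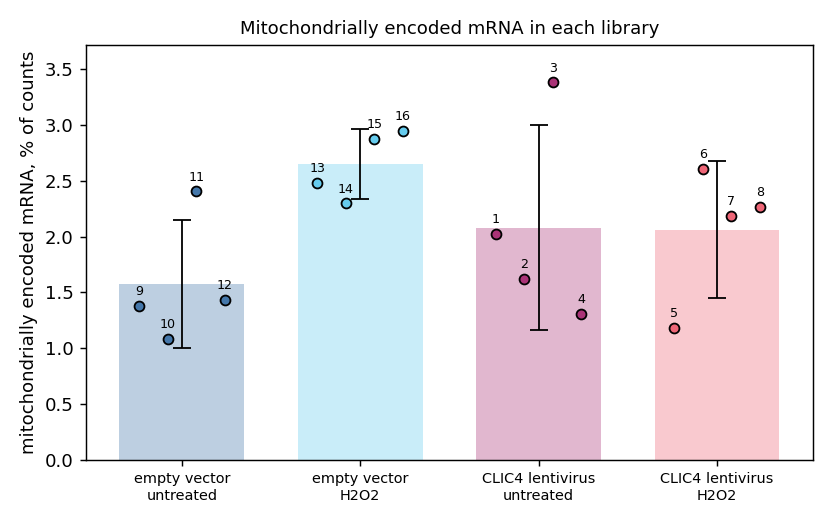
Points give the share of counts from mitochondrially encoded mRNA in percent (y axis) in each library, numbered, for the 4 groups (x axis); bars are group means and error bars 1 SD. Treated empty-vector libraries lie between 2.3 and 2.95, untreated ones between 1.08 and 1.43 except library 11 at 2.41, and lentivirus libraries spread from 1.18 to 3.38.

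The camera test with its preset correlation also called 5 lists lower in treated empty-vector cells, each with adjusted p = 0.68 with an estimated correlation. Heat shock genes had a median of -0.57 (0 of 18 called, 5 lower adjusted over the list alone), NF-kB targets -1.28 (0 of 16, 8 lower adjusted over the list alone), immediate early genes -1.10 (0 of 19, 0 adjusted over the list alone), complexes II to IV -0.14 (0 of 26, 0 adjusted over the list alone) and ribosomal proteins -0.30 (0 of 80, 0 adjusted over the list alone). Members include Hspa1a, a heat shock protein 70 gene (-6.29), Tnfaip3 (-3.05) and Fos (-3.87), none called. Library 11 held 229 CPM of Hspa1a, 464 of Tnfaip3 and 101 of Fos; without it these changes were 0.12, 0.14 and 0.03 and the list medians -0.03, 0.02, 0.03, -0.01 and -0.04, none of the 5 lists was called, 1 immediate early gene was higher and 0 other members of these lists were called over all genes or adjusted over the list alone; complexes II to IV were not called without library 10 either (adjusted p = 0.0613). Called without library 11 were interferon-stimulated genes (median -0.12, adjusted p = 3.64e-06) and DNA replication (-0.09, 0.0146), at adjusted p = 0.922 with an estimated correlation.

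In the lentivirus cells, too, the planned edgeR test called no gene with H2O2, and other fits named below called some. Values for the oxidant genes were 0.09 for Hmox1, -0.21 for Nqo1, -0.04 for Txnrd1, -0.09 for Gclm, 0.01 for Cat and 0.04 for Sod2, and for the stress genes 0.02 for Cdkn1a, -0.09 for Atf4 and -0.02 for Ddit3, all with edgeR adjusted p = 1. Gdf15 had 1 count in treated and 0 in untreated lentivirus libraries, and Clic5 2 and 3 counts, so that no fold is given. Clic1 stood at 246 ± 5.32 CPM treated and 257 ± 12.9 untreated (SD, n = 4 each).

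The edgeR test called 0 genes, with 255 at an unadjusted p under 0.05, and without library 11 again 0, with 2135 at that level. DESeq2 called 0 higher and 1 lower, limma on log2(FPKM + 1) without a filter 1 and 1 and limma voom with library weights 3 and 28. A fit on the lentivirus libraries alone called 20 higher and 101 lower. Over 6 simulated data sets, edgeR with 16 libraries recovered 34% to 60% of genes changed 1.5-fold in this comparison, and without library 11 96% to 100%, where 1.57% to 5.88% of all calls were of unchanged genes.

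The preset camera test called 10 lists in lentivirus cells, with small medians and 0 members called over all genes or adjusted over the list alone. Lower were genes of G2 and mitosis (median log2 change -0.25; Ccnb1 -0.29, Ccnb2 -0.29), DNA replication (-0.18; Mcm5 -0.32), cholesterol synthesis (-0.12; Hmgcs1 -0.13), complex I (-0.10; Ndufa5 -0.18), complexes II to IV (-0.12), ATP synthase (-0.13), cytosolic (-0.12) and mitochondrial ribosomal proteins (-0.07) and antioxidant enzymes (-0.07). Glycolysis and hypoxia genes were higher (0.08; Hk2, hexokinase 2, 0.21). None was called otherwise, the smallest value being adjusted p = 0.0759 with an estimated correlation for cholesterol synthesis and the largest adjusted p = 0.593 with an estimated correlation for cytosolic ribosomal proteins. The call of antioxidant enzymes (adjusted p = 0.0211) ended without library 2, 4 or 7 (0.0646, 0.107 and 0.109). Without library 11 the same number of lists was called, none below adjusted p = 0.352 with an estimated correlation, and adjusted over the list alone 23 genes of G2 and mitosis, 13 of cholesterol synthesis, 15 of complexes II to IV, 8 of ATP synthase, 7 of complex I, 31 cytosolic and 1 mitochondrial ribosomal protein genes were lower, 4 glycolysis and hypoxia genes were higher, and 0 antioxidant and 0 DNA replication genes were.

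The test of whether the response to H2O2 differed between the vectors called no gene. In 6 simulated data sets, edgeR with 16 libraries recovered 20% to 40% of genes changed 1.5-fold in this comparison, and 44% to 60% of those changed 2-fold. Without library 11 it recovered 90% to 100% of genes changed 1.5-fold, where 1.24% to 7.73% of all calls were of unchanged genes. The absence of calls with 16 libraries therefore does not show that the responses are alike. Clic4 had a log2 difference of -0.73 (edgeR adjusted p = 0.658; -0.09 without library 11), mt-Nd2 0.98, Ccnb2 0.47 and Cdc20 0.31, each at edgeR adjusted p = 0.658. By edgeR 0 genes were called, with 859 at an unadjusted p under 0.05; DESeq2 called 1 higher and 14 lower, limma on log2 FPKM 0, and limma voom with library weights 16 and 27. Without library 11 edgeR called 10 higher and 18 lower, and without library 14 it called 1 higher. With library 11 left out and the mitochondrial mRNA share as a covariate it called 0 and 0. That covariate takes up part of the treatment difference in empty-vector cells, so the lost calls do not show that the share explains them. No gene was shared by calls of H2O2 in both kinds of cells, as there were none, and the log2 changes of the 2 responses correlated over genes at r = -0.009.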

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

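Of the tests in this part, the voom fit with library weights and the fit without library 11 with the mitochondrial share as a covariate were chosen after the results were seen. So was the wider set of genes in the test for mixed-in cells. The explanations for library 11 were also raised from the data, with their bounds written before each test was run.

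In 216 groups of 4 values, the gap between the extreme library and its nearest neighbour, divided by the range, passed the 95% limit of Dixon's test 41 times. For independent groups that limit would give about 10.8. These groups share libraries, and many of their genes were named from these same data. Single counts can also give a gap share of 1, so the 10.8 is not a chance expectation here. Library 11 was the extreme in 28 of the 41. For library measures these were structural RNA share (0.984), share of the top genes (0.964) and scaling factor (0.984, at 0.721). For genes in untreated empty-vector cells the gap shares were Srgn 0.974, Gfpt2 0.985, Anpep 0.957, Gsdmd 0.972, Sprr1a 0.998, Fcho1 0.845, Nrk 0.903, Tmtc2 0.83, Clic1 0.861, Clic4 0.964, Clic5 0.966, Mthfd2 0.913, Edem1 0.861, Ccl2 0.991 and Nr4a1 0.984. For the oxidant and stress genes they were Hmox1 0.838, Nqo1 0.949, Txnrd1 0.937, Cat 0.847, Cdkn1a 0.942, Atf4 0.972 and Gdf15 0.94, and for Hspa1a 0.998, Tnfaip3 0.996 and Fos 0.996.

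The other 13 were spread over libraries, and several rest on single counts. In lentivirus cells they were structural RNA (0.901, library 2) and Clic4 (0.876, library 2) and Uox (1, library 4) untreated, and Gfpt2 (1, library 8), Anpep (0.883, library 5), Uox (0.883, library 5), Gsdmd (1, library 6), Sdf2l1 (0.857, library 6) and Cgn (0.868, library 8) treated. In treated empty-vector cells they were Slc40a1 (0.894, library 13), Fam135b (0.873, library 13), Nrk (1, library 14) and Tmtc2 (1, library 14).

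Library 11 differed from libraries 9, 10 and 12 in 4287 genes by at least 2-fold, with Rn7sk, Hspa1b, Arc, Ptgs2 and Akr1b3 among the highest. Lentivirus cells mixed into it would need a share of 0.513 to give its Clic4 level, but 6 genes with at most 3 counts in libraries 9, 10 and 12 reached a median share of 0 of their lentivirus level, which argues against such a mixture. In a wider set of 43 genes at under 5% of the lentivirus level that share was 0.0014. Another 65 genes at under 5% of the empty-vector level in lentivirus cells stood in library 11 at a median of 0.493 of their empty-vector level. Dilution by about 0.513 would also give such a median, but the values were spread widely, with quartiles of 0.315 and 0.954. A bias by transcript length and GC content is argued against as the whole cause, since 89.74% of the 4287 genes still differed after that trend was removed. What stays open is a different state of this culture or its RNA. Osmotic response genes were higher, with a median log2 ratio of 1.77 over the 6 measured of 7 (Hspa4l 3.65, Nfat5 2.50, Slc38a2 2.42, Slc5a3 1.11, Slc6a6 0.45, Slc6a9 0.08), above that of 10000 random lists of like expression. Medians of other lists were also high in library 11, at 1.56 for heat shock genes, 2.29 for NF-kB targets and 2.40 for immediate early genes. Random lists therefore cannot part osmotic stress from another stress. Hyperosmotic stress is 1 candidate explanation, found and tested on the same library.

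Many genes separated the vectors. Of 35 splits of the 8 libraries of a comparison, only the real one gave as many called genes. The counts were 4426 against at most 0 in the others in untreated cells, and 10491 against at most 0 in treated cells. This argues against a chance split of these libraries, at the lowest share that 35 splits allow. It does not cover chance differences between cultures, since the libraries of a group may be repeats of a culture. Subtracting the median of 50 neighbouring genes left 96.38% of the called 2-fold genes in treated cells. This argues against copy number of broad segments as the whole cause of these 2-fold differences. A gain or loss of a few genes would hardly move that median, so it was not tested. Removing a trend in length and GC content left 95.13% of the same genes. This argues against these biases as the whole cause of the 2-fold differences. Called genes that differed by less than 2-fold were not tested in these ways. Immune, fibroblast or endothelial cells are argued against too, since at most 2 markers of any of these lists lay over 10 CPM (without TMM scaling). The vector itself, the genotype and a separate history of the cells remain open, since this design cannot part them. On the genotype the labels conflict, with sample descriptions that call empty-vector libraries CLIC4 knockout and lentivirus libraries wild type.

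The larger share of mitochondrially encoded mRNA in treated empty-vector libraries may reflect an axis that also separates replicates. The difference between untreated lentivirus libraries 3 and 4, which differ most in that share, correlated with the response of empty-vector cells over 10466 nuclear genes at r = 0.416, between the bounds set for a yes and a no, so the explanations cannot be told apart; other pairs of that group gave 0.044 to 0.419. H2O2 as the biological explanation remains open.

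The difference of the H2O2 responses was called by the preset camera test for 7 lists, namely heat shock (adjusted p = 0.00168), mitochondrially encoded (0.00275), NF-kB targets (0.00759), G2 and mitosis (1.46e-07), DNA replication (0.0144), immediate early (0.00452) and ribosomal protein genes (0.00244). None was called otherwise, with the smallest adjusted p = 0.621 with an estimated correlation, and 0 members of these lists were called. The medians were -0.54, 0.57, -1.06, 0.38, 0.20, -1.17 and -0.18; without library 11 they were -0.02, 0.94, -0.02, 0.21, 0.10, -0.05 and 0.08. The calls of heat shock, NF-kB, immediate early and DNA replication genes ended without library 11 (adjusted p = 0.698, 0.938, 0.951 and 0.055), and ribosomal protein genes were then called in the other direction (2.1e-04). Called without it, but not with it, were interferon-stimulated genes lower (2.86e-05), and complex I (0.00811), complexes II to IV (0.00356), cholesterol synthesis (0.00356) and mitochondrial ribosomal proteins (0.00981) higher. Each call without library 11 had adjusted p = 0.915 with an estimated correlation. The call of mitochondrially encoded genes also ended without library 10 (0.088) or 12 (0.0593), and that of DNA replication without library 5 (0.0569), 12 (0.22) or 16 (0.167).

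The splits were fitted on the compared libraries alone. For H2O2 in empty-vector cells the real count was 0 and the highest other 0, so that all 35 splits reach it by construction, and the comparison says nothing about chance. Without library 11, 1 of 35 splits reached the real count, 329 genes against at most 121. This is the lowest share that 35 splits allow, not adjusted over the comparisons, so chance is not excluded for this count. Chance differences between cultures are not covered, since the libraries of a group may be repeats of a culture. The fit on 15 libraries called 18 higher and 17 lower. With the mitochondrial share as a covariate, which takes up part of the treatment difference itself, it called 0 and 0. For H2O2 in lentivirus cells 2 of 35 splits did, with 121 against 125 for the highest other, libraries 1, 3, 6 and 8 against the rest, so chance cannot be excluded. For the difference of responses the real count was 0 and the highest other 0, so that all 100 splits drawn reach it by construction and say nothing about chance.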

How the results depend on the processing

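The voom fit with library weights and the fit without library 11 with the mitochondrial share as a covariate were chosen after the data were seen. Among individually named genes, 2430 values kept direction and side of the threshold, 17 lost the call, 7 gained it and 39 turned direction; among called lists 588 did, 74 lost it and 4 turned. Depth limits genes near 0 counts, and the spread between libraries, 23.1% with library 11 and 5.28% without, limits the others. No paired analysis was possible because no library number is shared by groups. The 10 CPM filter left 9558 genes in place of 14445; the causes of the changes below were not tested.

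Untreated empty vector minus lentivirus gave 2777 higher and 2330 lower genes at 10 CPM, 2430 and 1996 with the compared groups alone, and 5432 lower with voom weights. Of at least 2-fold genes there were 777 higher and 391 lower at 10 CPM, 620 and 540 with log2(FPKM + 1), 972 higher with log2(FPKM + 0.1), and 609 and 526 with log2(FPKM + 1) unfiltered. Leaving out 1 library gave 3041 to 5449 lower genes. Treated empty vector minus lentivirus gave 2102 higher and 1871 lower at 10 CPM, 5183 and 5308 with the groups alone, 5415 and 5502 with voom weights, 5260 and 5308 with the covariate, and 1886 lower with log2(FPKM + 0.1). At least 2-fold there were 577 higher and 282 lower at 10 CPM, 731 and 330 with log2(FPKM + 1), 683 lower with log2(FPKM + 0.1), and 721 and 326 unfiltered. Leaving out 1 library gave 2882 to 5347 higher and 2419 to 5432 lower. Library 11 set the upper end of each of these ranges.

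For H2O2 in empty-vector cells DESeq2 gave 27 higher and 11 lower and voom weights 72 and 44; leaving out 1 library gave 0 to 18 higher (18 without library 11, 1 without library 14) and 0 to 17 lower. In lentivirus cells the groups alone gave 20 higher and 101 lower, DESeq2 1 lower, log2(FPKM + 1) unfiltered 1 higher and 1 lower, and voom weights 3 and 28. For the difference of responses DESeq2 gave 1 higher and 14 lower, voom weights 16 and 27, and leaving out 1 library 0 to 10 higher and 0 to 18 lower.

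Lists called with an estimated correlation and by fry numbered 2 and 23 for untreated and 1 and 23 for treated empty vector minus lentivirus, and 0 and 0 for H2O2 in empty-vector cells, in lentivirus cells and for the difference. Leaving out 1 library gave 8 to 14, 6 to 10 and, for H2O2 in empty-vector cells, 3 to 9. Calls shared by untreated and treated cells numbered 1813 higher and 1524 lower at 10 CPM, 4917 and 4795 with voom weights, 4725 and 4541 with the covariate, and 1176 and 919 at least 2-fold in both; leaving out 1 library gave 2607 to 4859 and 2052 to 4721.

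Signs turned for uncalled log2 changes of H2O2 in empty-vector cells. Without library 11 the mitochondrial share separates the treated from the untreated of these libraries, so the covariate takes up part of the treatment difference itself. With voom weights these were Clic1 -0.038, Clic4 0.026, Hmox1 0.081, Nqo1 0.032, Gclm -0.068, Atf4 0.026, Ddit3 0.10, Gdf15 0.20, Hspa1a 0.27, Tnfaip3 0.18 and Fos 0.08, and with the covariate Clic4 0.023, Clic5 0.42, Nqo1 0.12, Gclm -0.039, Gdf15 0.29, mt-Nd2 -0.047, Hspa1a 0.16, Tnfaip3 0.21 and Fos 0.21. Gclm was at -0.006 with RLE size factors and with DESeq2. With the covariate the difference of responses of mt-Nd2 was -0.011. In lentivirus cells Ddit3 was at 0.01 with log2(FPKM + 1), filtered or not, and 0.012 with log2(FPKM + 0.1).

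Leaving out 1 library gave, in empty-vector cells, Clic1 -0.033 to 0.10, Fos -4.26 to 0.029, Gclm -0.046 to 0.055, Gdf15 -1.35 to 0.073, Hmox1 -0.53 to 0.012, Hspa1a -6.69 to 0.12, Nqo1 -0.63 to 0.083 and Tnfaip3 -3.42 to 0.14. In lentivirus cells it gave Cat -0.008 to 0.018, Cdkn1a -0.002 to 0.039 and Ddit3 -0.062 to 0.018. Adjusted p ran from 0.00193 to 0.329 for immediate early genes and 0.00303 to 0.46 for NF-kB targets in empty-vector cells, and from 0.00374 to 0.938 for NF-kB targets and 5.46e-06 to 0.0228 for ribosomal proteins in the difference of responses.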

Other observations

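Zinc finger genes of a cluster on chromosome 13 were lower with the empty vector. This region was singled out after its values were seen. All 24 measured Zfp genes between 67038596 and 67827002 (mm10) had lower levels in treated empty-vector than lentivirus cells, with 17 called lower and 0 higher and a median log2 change of -0.66. In untreated cells without library 11, 23 were called lower and 0 higher, with a median of -0.75. The other 320 measured Zfp genes were mostly lower too, 263 of them in treated cells. Their median there was -0.35, with 125 called lower and 22 higher. In untreated cells without library 11, 236 of these 320 were called lower and 37 higher, with a median of -0.40. Lower levels were therefore not particular to the cluster, though its medians were further below 0. The median over 50 neighbouring genes departed from that of all genes by up to 0.611, at this cluster, against at most 0.431 in 20 shuffles of gene order.

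Markers of other cell types were mostly near 0. Their levels here are CPM without TMM scaling, averaged over treated and untreated libraries of a vector, library 11 included. Among immune markers, Cd68 stood at 247 CPM with the empty vector and 84.6 with the lentivirus, while Ptprc was at 0 and 0.0266 and Tyrobp at 0 and 0.00228. Among endothelial markers, Cdh5, VE-cadherin, was at 3.62 with the empty vector and 83.5 with the lentivirus, and Egfl7 at 20.8 and 29.4, with Kdr at 0.0851 and 0.0516. Among fibroblast markers, Pdgfra was at 15.5 and 4.61 and Col1a1 at 3.04 and 8.67. The immune, endothelial and fibroblast lists were not called in untreated (camera adjusted p = 0.096, 0.269 and 0.73) or treated cells (0.15, 0.227 and 0.577). Without library 11 camera called the immune list higher (adjusted p = 0.0234 and 0.0391) and the endothelial list lower (0.00695 and 0.00273). These calls were at adjusted p = 0.173 and 0.18 with an estimated correlation for immune and 0.158 and 0.18 for endothelial markers.

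In library 11 interferon-stimulated genes were lower than in libraries 9, 10 and 12, with a median log2 ratio of -1.65 and 22 of 30 at least 2-fold lower, and genes of G2 and mitosis had a median of -0.96. Heat shock genes had a median of 1.56, NF-kB targets 2.29 and immediate early genes 2.40.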
